A study of Saccharomyces cerevisiae with 14 samples.

How the data were processed

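The study measured polyadenylated RNA of S. cerevisiae W303 in 14 libraries, by the labels 8 from 4 carbon sources (2 replicates each) and 6 from the Ptet-Rpb1 strain (1 per aTc dose). Total RNA was purified with a column kit and libraries were made by a sequencing company, per the labels' protocols. Reads were handled with fastp 0.23.1 and STAR 2.5.2b on the builds sacCer3 and R64, per the submitters' processing notes. The deposited values are TPM, computed by the authors over all rows of a table, and every library sums to nearly the same total. The program that made the TPM values, the annotation, the C. glabrata reference, any filter, the strandedness and the handling of reads that map to several places are not given in the sources used here. Raw reads were not analysed here, and values in 3 lines of each table were not used here.

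Rows with S. cerevisiae locus tags numbered 6003 in the carbon-source tables and 6474 in the aTc table, and all matched the reference annotation by locus tag. That annotation is of the R64 assembly, 1 of the 2 builds in the submitters' processing notes, and it supplied gene names, lengths and positions. Rows with C. glabrata locus tags and ERCC rows were taken as the spike-ins that the labels mention. The carbon-source values of replicates 1 and 2 were compared over 11275 rows: no row differed by more than 1e-05 TPM, so each pair was counted once. Which replicate the values belong to cannot be known from the tables. The planned limma models, set tests, F tests, replicate block and leave-one-replicate-out for the carbon sources, which need replicates, were therefore not run.

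Values were analysed as log2 of TPM plus a pseudocount of 1 TPM, in genes with a mean of at least 1 TPM over the set (5801 genes in the carbon sources, 5990 in the aTc series). TPM as deposited was the planned scale. Because the S. cerevisiae part of the total differs between libraries, the S. cerevisiae rows were also rescaled to the same total in every library (shares) or divided by the C. glabrata or ERCC total. These 3 scales were chosen after the data were seen. Shares are used for named genes and for lists. Counts of genes over all tested genes, and of list members by dose or by carbon source, are given on both scales, and overlaps between comparisons in share only.

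For the aTc series, a slope on log2 dose was fitted per gene with limma 3.58.1 (mean-variance trend, moderated test, two-sided, 4 residual degrees of freedom) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested on this fit with camera (preset correlation 0.01), and camera with an estimated correlation and fry served as alternatives. Correlations across the 6 libraries used exact permutation of the 720 pairings, two-sided. For the carbon sources, genes that differed at least 2-fold were counted, and list medians were placed among 10000 random lists matched on mean expression. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

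The 31 gene lists, the comparisons, the rule for named genes and most alternatives were fixed before the data were examined. The lists cover cytosolic ribosomal proteins, ribosome biogenesis, RNA polymerases I, II and III, general transcription factors, Mediator, translation factors, mRNA decay, galactose use, gluconeogenesis and the glyoxylate cycle, glycerol use, trehalose and glycogen metabolism, hexose transporters, maltose and sucrose use, glycolysis and fermentation, the tricarboxylic acid cycle, the nuclear-encoded respiratory chain, mitochondrially encoded genes, mitochondrial ribosomal proteins, beta-oxidation and peroxisome, stress response and heat shock, autophagy, cell cycle regulators, histones, the proteasome, amino acid biosynthesis, a-cell-specific and alpha-cell-specific genes, meiosis and sporulation, and strain marker genes. Some lists share members, such as PGM2 in galactose use and in trehalose and glycogen metabolism.

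The rule named RPO21, the 6 largest rises and 6 largest falls per comparison with glucose and for the aTc slope, the 3 largest of each for other pairs, and up to 4 members per list, with at least 10 TPM in the higher library, or on average over the 6 doses, for the largest changes. As the carbon sources have no test, size replaced the adjusted p there. GAL1 and URA3 in the aTc series were named after their values were seen, as was HSP12 by dose.

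The dose fit was tested on simulated data with 5990 genes: of 50 genes each with true slopes of 0.1, 0.2, 0.4 and 0.8 it recovered 14%, 70%, 92% and 100%, with 7 false calls among 145. The simulated noise was drawn independently per gene around a straight line. These rates therefore do not cover genes of a library that depart from the line together, and give no false-call rate for the real series. The placing of lists was tested on simulated lists of 20 genes: 1.5% of 200 unchanged lists lay in the lowest or highest 2.5% of random medians, and 55.5% of lists shifted by 0.5 were found. These lists were drawn gene by gene at random, whereas members of a real list can change together. The 1.5% is therefore not a chance rate for the real lists.

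Alternatives were pseudocounts of 0.1 and 10 TPM, no filter or a mean of at least 10 TPM, centring on the median gene, quantile normalization, the 3 scales above, limma without the trend, linear or ranked dose, the 3 higher against the 3 lower doses, leaving out each dose, and random lists matched also on gene length. TPM gives no counts, so no counting interval or detection limit could be computed. Genes with near-identical copies, and overlapping or antisense genes, are uncertain where the authors' counting may have split their reads.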

Results

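Messenger RNA of Saccharomyces cerevisiae W303, a laboratory yeast strain, was measured by RNA sequencing in 2 sets of libraries that also carried RNA of other origin as internal standards. In the first set the yeast grew on 1 of 4 carbon sources, glucose, galactose, glycerol or trehalose, and the labels give 2 replicates for each. The deposited values of this set are named carbon-limited, a condition that all 4 sources, glucose included, share. In the second set a strain named Ptet-Rpb1 received anhydrotetracycline (aTc) at 5, 10, 20, 50, 100 or 200 ng/mL, with 1 library per dose. Rpb1 is the largest subunit of RNA polymerase II, Ptet is a tetracycline-controlled promoter, and aTc is the drug that releases it. The tables give TPM, a transcript abundance corrected for gene length and library total, over the rows of S. cerevisiae, of the related yeast Candida glabrata and, in the aTc set, of the synthetic ERCC RNAs. How much of each standard was added, and to how many cells, is not given in the sources used here, so a ratio to a standard is not a value per cell.

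The tables for carbon-source replicates 1 and 2 held the same values: of 11275 rows, 2 differed in each library pair, by at most 4.0e-06 TPM. Each carbon source was therefore counted as 1 library, which gives 10 libraries in all, and the differences between carbon sources have no replicate error and no p-value. TPM tables carry no read totals, so the depth of each library is unknown. S. cerevisiae rows took 67.6% of the TPM in glucose, 68.8% in galactose, 47.9% in glycerol and 61.7% in trehalose. In the Ptet-Rpb1 strain they took 50.6% at 5, 63.9% at 10, 81.3% at 20, 91.4% at 50, 89.2% at 100 and 85.8% at 200 ng/mL. Because these shares differ so much, gene values are given as TPM with the S. cerevisiae rows of every library rescaled to the same total, called shares, with a pseudocount of 1 TPM on the log2 scale.

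RPO21 (YDL140C, chromosome IV, 205360 to 210561 on R64), the gene of Rpb1, rose at every step of the aTc series. Its share was 8.99 TPM at 5, 16.7 at 10, 27.7 at 20, 59.8 at 50, 134 at 100 and 242 TPM at 200 ng/mL, a 26.9-fold range. Relative to the C. glabrata total the range was 156-fold. In the carbon-source libraries RPO21 stood at 22.6 TPM in glucose, 27.2 in galactose, 17.1 in glycerol and 27.0 in trehalose. The log2 of RPO21 as deposited followed log2 dose with Pearson r = 0.999 (two-sided exact permutation of 720 pairings, p = 0.00278, Benjamini-Hochberg 0.00694 over 5 relations, n = 6), and Spearman rho was 1.00 (exact p = 0.00278, adjusted 0.00694). Without the 5 and 200 ng/mL libraries r was 0.999. The share gave r = 0.998 and the same exact p. The dose labels thus follow the titrated gene in all 6 libraries.

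The series asks how the total amount of mRNA changes between growth conditions. Relative to C. glabrata, S. cerevisiae RNA stood at 2.08 in glucose, 2.20 in galactose, 0.918 in glycerol and 1.61 in trehalose, which is 2.27-fold lower in glycerol and 1.3-fold lower in trehalose than in glucose. Scaled by the median C. glabrata row instead of the total, glycerol stood at 0.456 and trehalose at 0.703 of glucose. With no ERCC rows and 1 library per source, the ratio to C. glabrata could not be checked against a second standard here. In the Ptet-Rpb1 strain the ratio was 1.11 at 5, 1.88 at 10, 4.70 at 20 and 11.7 at 50 ng/mL, a 10.5-fold rise, and then 8.90 at 100 and 6.43 at 200 ng/mL, 5.77-fold above the lowest dose. Relative to ERCC it was 12.8, 30.4, 60.1 and 117 at the first 4 doses, a 9.13-fold rise, then 116 and 93.5. RPO21 itself kept rising from 50 to 200 ng/mL while both ratios did not.

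The ratio to C. glabrata followed log2 dose with r = 0.844 (two-sided exact permutation p = 0.0444, adjusted 0.0556, n = 6) and rho = 0.771 (exact p = 0.103, adjusted 0.128). The relation therefore did not pass after adjustment over the 5 relations. Without the 5 and 200 ng/mL libraries r was 0.895. The ratio to ERCC gave r = 0.890 (exact p = 0.0167, adjusted 0.0278), rho = 0.771 (exact p = 0.103, adjusted 0.128) and r = 0.948 without the extreme doses. The 2 standards against each other showed no straight-line trend with dose (r = 0.0626, exact permutation p = 0.900, rho = 0.200, exact p = 0.714, r = -0.598 without the extreme doses). Their ratio was not constant, however. C. glabrata per ERCC was 11.5 at 5, 16.2 at 10, 12.8 at 20, 9.93 at 50, 13.1 at 100 and 14.5 at 200 ng/mL. It was lowest at 50 ng/mL, where the ratio of S. cerevisiae to C. glabrata peaked. The 1.46-fold rise from 50 to 200 ng/mL exceeds the 1.3-fold difference of trehalose from glucose.

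**Figure D1:**
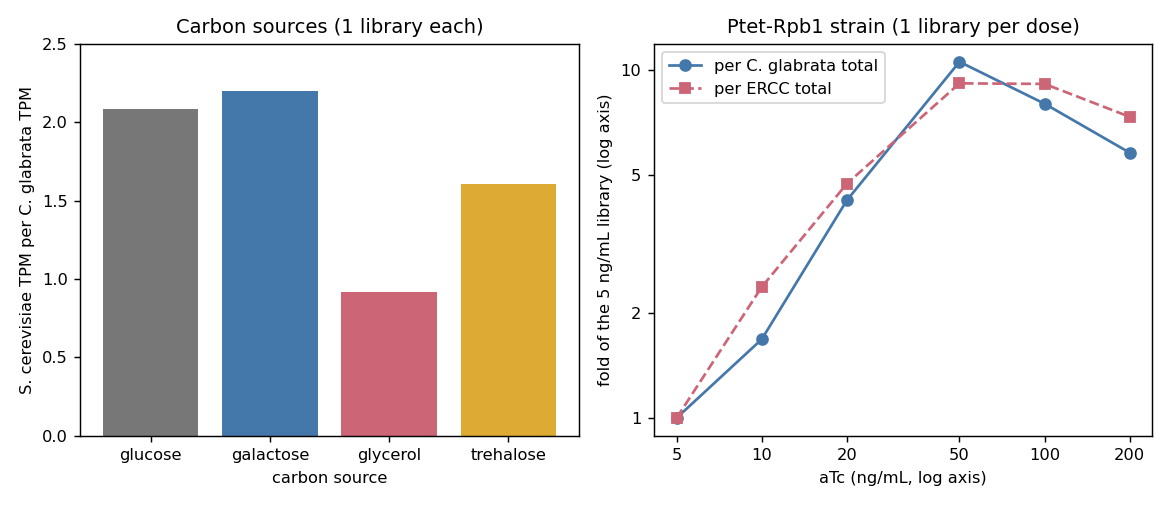
S. cerevisiae TPM per C. glabrata TPM in the carbon-source libraries (bars, left) and, relative to the 5 ng/mL library, per C. glabrata or ERCC total at each aTc dose (points, right, both axes logarithmic), with 1 library per bar or point. Glycerol has the lowest bar at 0.918, and the ratio to C. glabrata peaks at 10.5 times the lowest dose at 50 ng/mL.

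Within the S. cerevisiae RNA, the shares of many genes changed along the titration. The steepest rises were TDH1, a glyceraldehyde-3-phosphate dehydrogenase (slope 0.93 log2 units per doubling of aTc, SE 0.093, limma adjusted p = 0.00077), RCK1, a kinase of the oxidative stress response (0.90, SE 0.13), and RPO21 (0.87, SE 0.030, adjusted p = 2.2e-05). ADH5, an alcohol dehydrogenase, rose by 0.86, RGI1, an energy metabolism gene, by 0.85 and RTC2, a vacuolar transporter, by 0.82. TDH1 went from 9.65 TPM at 5 to 361 TPM at 200 ng/mL. The steepest falls were the tRNA genes SOE1 (-1.26, SE 0.099, adjusted p = 0.00073), SUP51 (-0.79) and SUP2 (-0.73), BTN2, a protein sorting factor (-0.68), the small nucleolar RNA SNR72 (-0.66) and SER3, a serine biosynthesis enzyme (-0.62). SOE1 went from 266 to 3.51 TPM. Relative to C. glabrata all 6 also had a negative slope, from -0.74 for SOE1 to -0.07 for SER3. tRNA genes have near-identical copies, so the split of reads among them is uncertain, as it is between TDH1 and its close paralogs. The libraries were of polyadenylated RNA, so rows of tRNA and small nucleolar RNA do not give the total levels of these RNAs.

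Of 5990 genes tested, 3506 had a dose trend in share at a limma adjusted p under 0.05, 1807 rising and 1699 falling. On the TPM as deposited, where the S. cerevisiae total itself grows with dose, 3313 genes had a trend, 3089 rising and 224 falling. Which direction held more genes depended on the scale: centred on the median gene 1697 rose and 1734 fell, and by quantile normalization 1415 rose and 1769 fell. In share the balance was near even and turned toward falling among genes with a mean of at least 10 TPM (1344 rising, 1623 falling), with the 3 higher against the 3 lower doses (950 and 1321) and without the 200 ng/mL library (1533 and 1592). The median gene had a slope of 0.14 as deposited, 0.00 in share, 0.52 per C. glabrata and 0.52 per ERCC. With 1 library per dose, the spread is the departure from a straight line in log2 dose, with 4 residual degrees of freedom. Without the 5 ng/mL library the counts fell to 2056 in share and 1560 as deposited, and with dose on a linear scale no gene passed under limma, although 2087 and 1288 had an unadjusted p under 0.05.

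The other subunits of RNA polymerase II did not follow RPO21. Among those shared by all 3 nuclear polymerases, RPC10 went from 923 to 379 TPM (slope -0.27), RPB10 from 941 to 373 TPM (-0.27) and RPB5 from 442 to 252 TPM (-0.16). The 6 subunits found only in RNA polymerase II had a median slope of -0.17 in share. Of the 12 subunits 9 fell and 1, RPO21, rose (camera adjusted p = 0.00300, down; adjusted p = 0.454 with an estimated correlation), with the same counts adjusted over the list alone. As deposited 2 fell and 2 rose, and per C. glabrata 0 fell and 6 rose. The median slope was -0.18 in share and -0.03 as deposited, but 0.37 per C. glabrata and 0.38 per ERCC. The mean was -0.08 in share and, pulled by RPO21, 0.06 as deposited, the opposite sign to the median there. RNA polymerase I (8 of 9 fell in share) and RNA polymerase III (8 of 10 fell) went the same way in share, but as deposited 0 fell and 1 rose in each. Their median slopes of -0.15 and -0.13 in share became positive per C. glabrata, 0.40 and 0.42, and their counts in share were the same adjusted over the list alone.

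**Figure D2:**
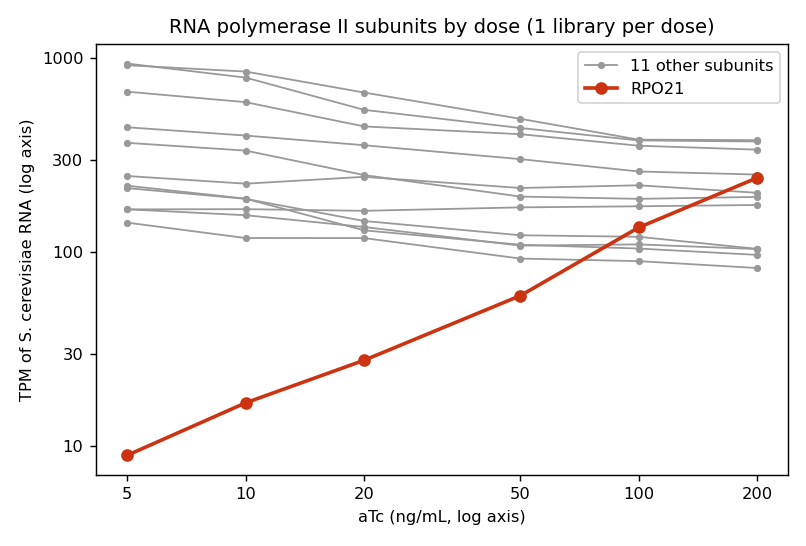
TPM of S. cerevisiae RNA (logarithmic axis) against aTc dose (logarithmic axis) for the 12 RNA polymerase II subunit genes, 1 library per dose, RPO21 in red and the other 11 in grey. RPO21 climbs from 8.99 to 242 TPM while the median subunit declines in share, a decline that turns into a rise per C. glabrata or ERCC.

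The proteasome, which degrades proteins, fell most uniformly: all 33 genes fell in share and 21 as deposited. Together they went from 1.73% of S. cerevisiae RNA at 5 to 0.678% at 50 ng/mL and stood at 0.706% at 200 ng/mL. RPT4, an ATPase of its cap, went from 555 to 149 TPM. Ribosome biogenesis genes, which build the ribosome, fell in 107 of 123 cases, with UTP18 going from 161 to 42.7 TPM. Cytosolic ribosomal proteins fell in 67 and rose in 8 of 137 cases and went from 31.1% to 23.6% of the RNA. General transcription factors fell in 22 of 32 cases, mRNA decay in 22 of 45 with 5 rising, translation factors in 16 of 37 with 5 rising, mitochondrial ribosomal proteins in 26 of 76 with 7 rising, and the nuclear-encoded respiratory chain in 15 of 39 with 5 rising. The last 2 lists were lowest at 50 ng/mL, at 1.06% and 0.833% of the RNA, and stood at 1.25% and 0.961% at 200 ng/mL. Most of the falls in these lists exist in share only. As deposited 17 ribosome biogenesis genes fell and 7 rose, and 6 general transcription factors fell and 2 rose, while none fell among cytosolic ribosomal proteins (26 rose), mRNA decay (16), translation factors (12), mitochondrial ribosomal proteins (29) or the respiratory chain (11). Per C. glabrata no member of these lists or of the proteasome fell, and 62 ribosome biogenesis and 115 cytosolic ribosomal protein genes rose.

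Other lists rose in share. Glycolysis and fermentation rose in 19 of 20 cases, from 4.25% of the RNA at 5 to 10.1% at 50 and 10.7% at 200 ng/mL. TDH2 went from 741 to 5779 TPM and ENO1, enolase, from 471 to 3216 TPM. Trehalose and glycogen metabolism, the storage carbohydrates, rose in 17 of 20 cases and hexose transporters in 10 of 14, with HXT4 going from 48.0 to 634 TPM. The rise was not steady in every list: hexose transporters took 0.447% of the RNA at 20, 0.301% at 50 and 0.729% at 200 ng/mL. Autophagy took 0.146% at 20 and 0.131% at 50 ng/mL, while trehalose and glycogen metabolism rose at every step. Autophagy rose in 21 of 30 cases with 1 falling, amino acid biosynthesis in 34 of 58 with 8 falling, histones in 8 of 10, maltose and sucrose use in 7 of 11, meiosis and sporulation in 12 of 19, and the alpha-cell-specific genes, markers of mating type, in 4 of 4. As deposited the rising counts were 20 for glycolysis and fermentation, 19 for trehalose and glycogen metabolism, 14 for hexose transporters, 27 for autophagy, 44 for amino acid biosynthesis with 1 falling, 9 for histones, 8 for maltose and sucrose use, 15 for meiosis and sporulation and 4 for alpha-cell-specific genes.

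By camera with a preset correlation of 0.01, 20 of 31 lists passed in share, 9 up and 11 down, against 15 as deposited, 8 up and 7 down. Camera compares a list with the other genes, so down means slopes below theirs and not by itself a fall. The adjusted p was 4.25e-21 for ribosome biogenesis, 7.79e-11 for the proteasome, 2.06e-07 for glycolysis and 1.98e-06 for cytosolic ribosomal proteins. With an estimated correlation no list passed: the smallest adjusted p was 0.454 in share and 0.880 as deposited. Adjusted over the list alone, 111 ribosome biogenesis genes fell, 20 glycolysis genes rose, 11 hexose transporters rose, 23 autophagy and 35 amino acid biosynthesis genes rose, 24 mRNA decay genes fell, and 17 mitochondrial ribosomal protein genes fell with 6 rising. The other passing lists kept their counts adjusted over the list alone. These falls are relative to the S. cerevisiae total: per C. glabrata or ERCC every list had a positive median slope, the lowest being the proteasome at 0.27 and 0.28. As deposited, the medians were positive for cytosolic ribosomal proteins (0.08), mRNA decay (0.08), translation factors (0.09), mitochondrial ribosomal proteins (0.08), the respiratory chain (0.09) and RNA polymerase III (0.02), and negative for the proteasome (-0.13), RNA polymerase II (-0.03) and ribosome biogenesis (-0.02) and, close to 0, for general transcription factors (-0.0053) and RNA polymerase I (-0.0035).

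The lists that did not pass went both ways or held few genes. Stress response and heat shock rose in 17 and fell in 8 of 42 cases, beta-oxidation and peroxisome genes rose in 7 and fell in 1 of 23, and gluconeogenesis and the glyoxylate cycle rose in 8 and fell in 2 of 20. Cell cycle regulators rose in 11 and fell in 8 of 35, Mediator rose in 4 and fell in 7 of 25, and the tricarboxylic acid cycle rose in 3 and fell in 4 of 15. Glycerol use rose in 5 of 6, galactose use in 3 of 4, a-cell-specific genes in 1 of 7 and mitochondrially encoded genes in 0 of 3. As deposited 25 stress response genes rose and 3 fell, 15 beta-oxidation, 21 cell cycle and 10 Mediator genes rose with none falling, 12 gluconeogenesis genes rose and 1 fell, 6 tricarboxylic acid cycle genes rose and 1 fell, and 5 glycerol use, 4 galactose use, 3 a-cell-specific and 0 mitochondrially encoded genes rose. Strain marker genes rose in 4 and fell in 1 of 5 in share, where LEU2 went from 5.67 to 75.3 TPM. As deposited 4 rose, and LEU2 went from 2.87 to 64.6 TPM. GAL1 and URA3 were listed at 0 in all 6 libraries.

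**Figure D3:**
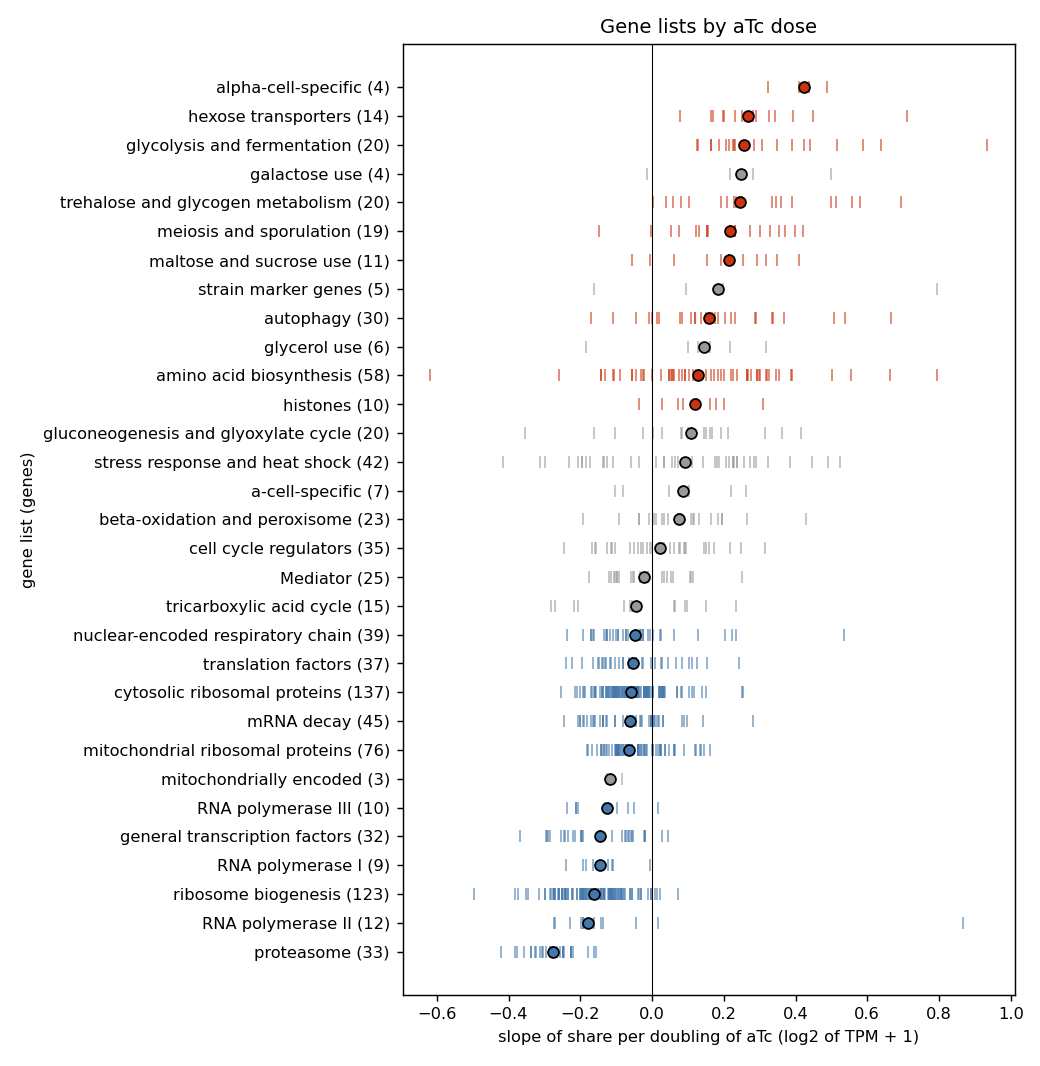
Slope of share per doubling of aTc (log2 of TPM + 1) for each tested gene (ticks) and the median of each list (circles), red where the list passed upward and blue where it passed downward by camera with a preset correlation of 0.01, while 0 lists passed with an estimated correlation. The proteasome lies lowest at -0.28, and every list median below 0 turns positive per C. glabrata or ERCC.

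In galactose, the genes that take up and convert this sugar rose most. GAL7, GAL1 and GAL10, which carry out its first conversions, rose by 10.77, 9.70 and 9.36 log2 units over glucose, GAL7 from 0.656 to 2897 TPM, and the transporter GAL2 rose by 9.02. GCY1, a glycerol dehydrogenase, rose by 6.04 and SPG4, a stationary-phase gene, by 5.84. The glucose-linked hexose transporters HXT3, HXT1 and HXT4 changed by -4.52, -2.94 and -2.29, HXT3 from 392 to 16.2 TPM. The mating genes MF(ALPHA)2 and SAG1 changed by -2.96 and -2.43, and AAC3, an ADP/ATP carrier, by -2.31. The tricarboxylic acid cycle (15 of 15 genes at least 2-fold higher, median 2.24) and the nuclear-encoded respiratory chain (38 of 39, median 1.95) rose nearly throughout, with the same counts as deposited and SDH2, a succinate dehydrogenase subunit, going from 60.8 to 642 TPM.

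Galactose use had a median of 7.04 in galactose, gluconeogenesis and the glyoxylate cycle 2.05, stress response 1.56, trehalose and glycogen metabolism 1.32, and mitochondrial ribosomal proteins 1.02 (43 of 76 at least 2-fold higher, 47 as deposited). Cytosolic ribosomal proteins had a median of -0.44 and went from 46.6% to 34.1% of the RNA, and ribosome biogenesis had -0.22. The median gene rose by 0.34 in share, 0.35 as deposited and 0.41 per C. glabrata, so medians near this value set no list apart. RNA polymerase II (0.05), Mediator (0.32), the proteasome (0.32), general transcription factors (0.16), mRNA decay (0.08) and cell cycle regulators (0.35) each turned negative when the libraries were centred on the median gene. Of 5801 genes, 961 differed at least 2-fold in share, 894 higher and 67 lower, against 936 as deposited, 875 and 61. Among C. glabrata rows with a mean of at least 10 TPM, which come from the standard, 0.874% differed 2-fold, against 14.9% of S. cerevisiae rows.

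In glycerol, the largest rises were in SIP18, SPG4, GRE1, DDR2, ADH2 and HSP12. SIP18, a desiccation-linked phospholipid-binding protein, was listed at 0 in glucose and stood at 2674 TPM. SPG4 rose by 10.47, the hydrophilin GRE1 by 10.35, the stress gene DDR2 by 10.22, ADH2, which oxidises ethanol, by 10.00 and the membrane protein HSP12 by 9.53, with ADH2 going from 9.61 to 10858 TPM. Falls were led by MF(ALPHA)2 (-4.98), HXT3 (-4.67), the ammonium permease MEP2 (-4.33), the arginine enzyme ARG3 (-3.73), ARI1, a reductase (-3.63), and IRC7, a cysteine lyase (-3.19). The glycerol transporter STL1 rose by 6.64, GUT2 and GUT1, which feed glycerol into glycolysis, by 5.48 and 4.59, and POT1, of beta-oxidation, by 6.12.

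The glycerol medians over glucose were 4.85 for gluconeogenesis and the glyoxylate cycle, 4.47 for glycerol use, 4.21 for stress response, 3.14 for the tricarboxylic acid cycle, 3.06 for beta-oxidation and peroxisome, 2.5 for trehalose and glycogen metabolism, 2.15 for the respiratory chain and 1.52 for hexose transporters. These 8 were positive under every scaling tried. Cytosolic ribosomal proteins had -0.88 and 25% of the RNA, RNA polymerase I -0.77, ribosome biogenesis -0.70, RNA polymerase II -0.44, translation factors -0.43, amino acid biosynthesis -0.42 and RNA polymerase III -0.38, all negative under every scaling. The mitochondrial ribosomal proteins rose in share (0.99) and fell per C. glabrata (-0.18). Galactose use (0.88, -0.03 per C. glabrata), Mediator (0.50, -0.61), the proteasome (0.27, -0.90), general transcription factors (0.24, -0.87) and histones (0.09, -1.09) also changed sign.

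In glycerol against glucose the direction of the median gene depended on the scale: it rose by 0.43 in share, was at -0.04 as deposited and at -0.66 per C. glabrata. In share 1721 genes differed at least 2-fold, 1507 higher and 214 lower, as deposited 1542, 871 and 671, and per C. glabrata 2392, 514 and 1878. C. glabrata rows differed 2-fold in 1.14% of cases, against 28.7% of S. cerevisiae rows.

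In trehalose SIP18, GRE1, SPG4 and DDR2 were again among the largest rises. SIP18, listed at 0 in glucose, stood at 5855 TPM, GRE1 rose by 11.84, SPG4 by 11.14, DDR2 by 10.90, the chaperone HSP26 by 10.37 and RGI2, an energy metabolism gene, by 10.09. ATH1, which splits trehalose outside the cell, rose by 4.42, from 1.98 to 62.7 TPM, the hexose transporter HXT5 by 7.69 and the autophagy gene ATG8 by 4.29. The falls included short genes, LSM5, an RNA decay factor, and SMX2, a splicing protein, both listed at 0 in trehalose, along with EFG1, of ribosome biogenesis (-4.80), TOM7, of mitochondrial import (-4.73), HXT3 (-4.44) and the allantoin enzyme DAL3 (-4.14). The 9 genes listed at 0 in trehalose with at least 10 TPM in the other 3 libraries were all under 400 nt, and falls of short genes in this library are uncertain. The 4 such genes in the other libraries were also all under 400 nt, so length alone does not set trehalose apart.

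Medians in trehalose over glucose were 4.80 for stress response, which went from 0.629% to 9.63% of the RNA, 4.32 for glycerol use, 4.26 for gluconeogenesis and the glyoxylate cycle, 3.51 for beta-oxidation and peroxisome, 2.92 for trehalose and glycogen metabolism, 2.29 for autophagy, 2.28 for the tricarboxylic acid cycle, 2.11 for maltose and sucrose use, 2.10 for hexose transporters, 2.03 for meiosis and sporulation and 1.57 for the respiratory chain. Cytosolic ribosomal proteins had -1.48, with 109 of 135 at least 2-fold lower (115 as deposited), and took 16.5% of the RNA. RNA polymerase I had -1.10, ribosome biogenesis -0.79, RNA polymerase II -0.65 and RNA polymerase III -0.51. None of these changed sign under any scaling tried. Mitochondrial ribosomal proteins had 0.38, which turned to -0.43 when centred on the median gene, and glycolysis and fermentation had 0.73, which turned to -0.08. The mRNA decay genes (0.30) turned negative per C. glabrata (-0.06). The median gene rose by 0.64 in share, 0.50 as deposited and 0.28 per C. glabrata. In share 2684 genes differed at least 2-fold, 2154 higher and 530 lower, against 2476 as deposited, 1893 and 583. The balance turned when the libraries were centred on the median gene, 1006 higher and 1301 lower, and by quantile normalization, 978 and 1181. Here 5.71% of C. glabrata rows also differed 2-fold, against 45.6% of S. cerevisiae rows.

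**Figure D4:**
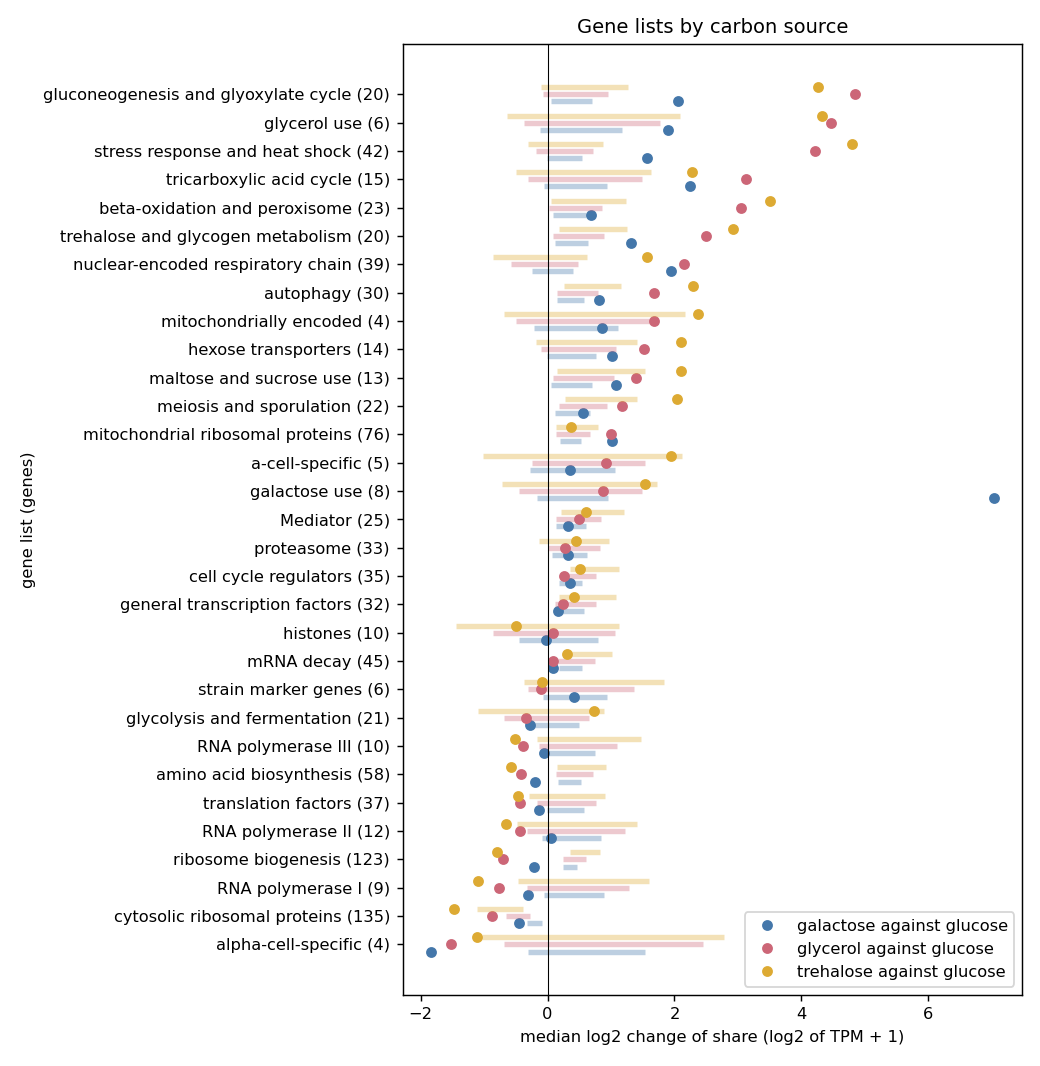
Median log2 change of share against glucose for each gene list (circles), with the range holding the central part of the medians of 10000 random lists matched on expression (bars), from 1 library per carbon source. Galactose use stands at 7.04 in galactose and cytosolic ribosomal proteins at -1.48 in trehalose, while medians such as that of mitochondrial ribosomal proteins in glycerol (0.99) change sign with the scaling (-0.18 per C. glabrata).

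As a description of these libraries, each list median was placed among those of 10000 random lists of the same size matched on mean expression. In share, 20 of 31 lists lay in the lowest or highest 2.5% of the random medians in galactose, 21 in glycerol and 20 in trehalose, against 20, 22 and 20 as deposited. Cytosolic ribosomal proteins, ribosome biogenesis and amino acid biosynthesis lay at percentile 0 in all 3 comparisons. Alpha-cell-specific genes had medians of -1.84, -1.52 and -1.11 in galactose, glycerol and trehalose. The a-cell-specific genes had 0.35, 0.92 and 1.95, with -0.12 in galactose when centred on the median gene and -0.02 in glycerol per C. glabrata, and mitochondrially encoded genes 0.86, 1.67 and 2.37. Because polyadenylated RNA was measured, the latter values do not give total levels of mitochondrially encoded RNA. Strain marker genes had 0.42, -0.11 and -0.09, with -0.02 in galactose when centred on the median gene, where URA3 went from 590 TPM in glucose to 149 in glycerol and 107 in trehalose.

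Between the other carbon sources, the GAL genes set galactose apart. GAL7, GAL10 and GAL1 changed by -10.18, -8.75 and -8.47 from galactose to glycerol and by -9.68, -7.88 and -7.76 from galactose to trehalose. GRE1, SIP18 and ADH2 rose by 7.52, 6.68 and 6.56 in glycerol, and GRE1, HSP26 and SIP18 by 9.01, 8.24 and 7.81 in trehalose. From glycerol to trehalose, ECM12 and the meiotic recombination gene SAE3 rose by 3.62 and 2.95, PAU16, a seripauperin listed at 0 in glycerol, stood at 22.3 TPM, and the short genes ELC1, MVB12 and HUG1 were listed at 0 in trehalose. Glycerol against galactose gave 773 genes at least 2-fold different in share, 592 higher and 181 lower, but 1032 as deposited, with the balance the other way, 297 higher and 735 lower. Per C. glabrata 162 were higher and 3323 lower, while centred on the median gene 467 were higher and 241 lower, and by quantile normalization 450 and 274. Trehalose against galactose gave 1788, 1241 higher and 547 lower, and 1670 as deposited, 997 and 673, but the balance turned per C. glabrata (724 and 1042), centred on the median gene (768 and 940) and, barely, by quantile normalization (795 and 806). Trehalose against glycerol gave 843, 535 higher and 308 lower, 1324 as deposited, 1150 and 174, and 2721 per C. glabrata, 2613 and 108, but 274 were higher and 459 lower when centred on the median gene, and 364 and 385 by quantile normalization. In these 3 comparisons the direction that held more genes thus depended on the scale. Over the 4 carbon sources, 3189 genes differed at least 2-fold between some pair in share and 3360 as deposited.

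The responses to the 3 other carbon sources were compared across genes. Of the genes at least 2-fold higher than in glucose, 752 were shared by galactose and glycerol, 701 by galactose and trehalose and 1306 by glycerol and trehalose, where independent sets of the same sizes would share 232, 332 and 560. Over 5801 genes, r was 0.719, 0.619 and 0.855 for these pairs. The 3 responses share the single glucose library, which alone gives r = 0.5 in simulated unchanged libraries of equal spread. Among C. glabrata rows r was 0.501, 0.172 and 0.340 for the same pairs, so 0.5 need not hold for the pairs with trehalose. The covariances were 0.738, 0.785 and 1.71, against a simulated 0.0440. The simulated spread is that of C. glabrata rows, which holds no variation between cultures, so the excess does not show a shared response. Genes are not independent replicates, and with 1 glucose library the shared part could not be removed.

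Of 1738 genes that rose in share with aTc and were also tested in the carbon sources, 416 (23.9%) were at least 2-fold higher in galactose than in glucose, 710 (40.9%) in glycerol and 949 (54.6%) in trehalose, against 15.2%, 25.6% and 36.8% of all 5680 genes tested in both sets. Of 1611 falling genes it was 98, 171 and 302 (6.08%, 10.6% and 18.7%). Across the 5680 genes the aTc slope correlated with the response at r = 0.158 for galactose, 0.268 for glycerol and 0.285 for trehalose. In 100 orders of the 6 doses, the real one included, 52, 43 and 41 gave a correlation as large, so these relations did not stand out from chance orders of the doses.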

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

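The scalings to S. cerevisiae, C. glabrata and ERCC totals, the leave-one-dose-out of the spike-in ratio and lists, and the matching on length were chosen after the results were seen. Over all results, 153 alternative values were computed: 122 stayed on the same side of their threshold, near their value or within 1.5 times of a count, and 31 did not. No correlation reversed. Counts were compared by their total alone: of 83 alternative gene counts divided into higher and lower, the balance of higher and lower genes turned in 17, of which 13 kept a total within 1.5 times, and of 27 list counts it turned in 7. No paired analysis was possible because the replicates held the same values and each dose has 1 library. The limma fits, set tests, F tests, replicate block, leave-one-replicate-out, minimum fold change and comparison of replicate 1 with replicate 2 planned for the carbon sources were not run for the same reason.

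With a pseudocount of 10 TPM, which shrinks low genes by construction, the counts of genes at least 2-fold different (from TPM as deposited) were 391 for galactose, 925 for glycerol and 1510 for trehalose against glucose, 512 for glycerol and 1020 for trehalose against galactose, 499 for trehalose against glycerol and 1976 over the 4 sources, and r between galactose and trehalose was 0.564. Quantile normalization gave 576 for galactose against glucose and 749 for trehalose against glycerol. Trehalose against glycerol also gave 733 centred on the median gene and 843 rescaled to S. cerevisiae. Scaled to C. glabrata, glycerol gave 2392 against glucose and 3485 against galactose, trehalose 2721 against glycerol, and the 4 sources 5173. Scaling to C. glabrata shifts the genes of a library together. The median gene then stood at -0.66 for glycerol against glucose, -1.10 for glycerol against galactose and 0.94 for trehalose against glycerol. Apart from the pseudocount and this shift, the cause was not tested.

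The aTc count was 5160 per C. glabrata and 5661 per ERCC, where the rising total lifts nearly every gene. The 3 higher against the 3 lower doses gave 1108 as deposited and 2271 in share. Linear dose gave 0 on both scales with limma, with 1288 and 2087 genes at an unadjusted p under 0.05. Leaving out each dose gave 1560 to 3636 genes as deposited and 2056 to 3726 in share, the lowest without 5 ng/mL in both cases. The other 5 gave at least 2625 and 2624 from the same number of libraries, so having fewer samples does not by itself explain the low counts without 5 ng/mL, and the cause was not tested.

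RPO21 kept its relation with dose throughout (r = 0.999 to 1.00 leaving out each dose, 0.890 with linear dose). The ratio to C. glabrata gave r = 0.716 to 0.946 leaving out each dose, and before any adjustment only r = 0.946, without 200 ng/mL, had an exact permutation p under 0.05 (0.0333, range 0.0333 to 0.183 over the 6), against 0.0444 with all doses, which did not pass after adjustment. Lists passing for aTc were 19 to 22 leaving out each dose in share and 12 per C. glabrata or ERCC. By fry, which tests a list by itself, 20 passed in share (11 up, 9 down) and 18 as deposited (17 up, 1 down). By camera with an estimated correlation 0 and 0 passed, where the smallest unadjusted p was 0.0526 in share and 0.0784 as deposited. Matched also on length, 21, 21 and 19 lists stood apart in galactose, glycerol and trehalose. Without read counts, what depth limits cannot be stated.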

Other observations

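The tests on the spike-in ratio, on RNA polymerase II against I and III, on gene length and on the order of the doses were chosen after the results were seen. The set test of the polymerase subunits, though not their percentiles, was known before the tests of expression, length and GC content. The test of depth was set before its result, while the comparison of excess variance with TPM was added after it.

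S. cerevisiae RNA per C. glabrata rose 10.5-fold from 5 to 50 ng/mL aTc and was lower at 100 and 200 ng/mL. Some causes of the rise are argued against: ERCC, a second standard, gave a 9.13-fold rise, and 85.7% of the tested genes rose per C. glabrata. Neither an error in 1 standard nor a few abundant genes would therefore explain it alone. The median C. glabrata row gave a rise 1.04 times that of the C. glabrata total. This comparison does not bear on the cause, as S. cerevisiae reads misassigned to C. glabrata rows would lower the ratio. The fall from 50 to 200 ng/mL is less clear, since the ratio to ERCC at 200 was 0.801 of that at 50 ng/mL, against 0.548 for C. glabrata. An error in the amount of C. glabrata added and a lower RNA content cannot be told apart there with 1 library per dose. A rise of mRNA with Rpb1 supply is a candidate explanation of the first part, but aTc dose and Rpb1 level change together, cell numbers are not given, and other effects of the drug remain untested.

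Of the 11 other RNA polymerase II subunits 9 fell in share while RPO21 rose, and the median slope of the 11 was -0.19. Expression level is argued against as the whole cause, because this median lay at percentile 0.370 of lists matched on expression, and so are length and GC content, because after removal of their trends it lay at percentile 0.0700. The random lists were drawn gene by gene, so these percentiles do not allow for subunits that change together and are not chance rates. With an estimated correlation, camera passed 0 lists in share. A change particular to RNA polymerase II stays open: the median slope of the 6 subunits found only there differed by -0.0367 from that of 19 subunits of RNA polymerases I and III (two-sided permutation p over genes 0.392), and a p of this size does not show that they did not differ. The fall may belong to a wider fall of the transcription and ribosome-building genes in share. It turns positive per C. glabrata or ERCC.

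In the trehalose library C. glabrata rows spread more than elsewhere and 9 short genes were at 0. Of 2146 C. glabrata rows with at least 10 TPM in the other 3 libraries, 10 were also at 0 there. By the same rule 0 C. glabrata rows were at 0 in glucose, galactose or glycerol. Low depth as the whole cause is argued against: among rows with at least 200 TPM the SD against glucose was still 2.58 times that of galactose. From the range of 10 to 50 TPM to that above 200 TPM, median TPM rose 35.3-fold but the excess variance fell only 2.70-fold, where counting noise would fall about in proportion. Short length may matter for the zeros, as 100% of the 9 genes were under 400 nt against 8.13% of comparable genes, but the 4 such genes in the other libraries were all short too, so the test could hardly come out otherwise and decides nothing. No biological explanation was tested, since C. glabrata was the standard in every library.

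The number of genes with an aTc trend was set against other orders of the doses. Of 100 orders, 1 (the real one) gave as many genes, 3313 as deposited with 3186 in the highest other order, and 3506 in share with 2838 in the highest other. At this number of orders, chance order of the doses is argued against, although some other orders come close as deposited. The test cannot tell dose from anything else that changed in the same order.

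tRNA rows took 1961 TPM of the S. cerevisiae share at 5 ng/mL and 408 TPM at 200 ng/mL, and of 117 tested 63 fell and 16 rose. Per C. glabrata the tRNA total at 200 was 1.2 times that at 5 ng/mL, with a 1.81-fold range over the 6 libraries, and for ribosomal RNA rows it was 21.6 times with a 43.8-fold range. As polyadenylated RNA was measured, these rows do not give the total levels of tRNA or ribosomal RNA. Among protein-coding genes, the aTc slope in share had rho = -0.377 with mean TPM, a value that 13 of 100 orders of the doses matched or exceeded, -0.0353 with gene length and 0.0268 with GC content. The stress gene HSP12 had its highest share, 800 TPM, at 20 ng/mL, against 76.3 at 5 and 20.1 at 50 ng/mL. LEU2 rose from 5.67 TPM at 5 to 86.4 TPM at 50 ng/mL.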
